A study of Mus musculus with 2 samples.

How the data were processed

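The series holds total RNA sequencing of mouse embryonic limb at 15.5 days after conception, strain B6NCrl per the labels. There was 1 group with 2 biological replicates, each a separate pool of embryos of both sexes: 78 embryos in replicate 1 and 62 embryos in replicate 2. Per the labels' protocols, RNA was extracted with the Ambion mirVana method, RNA longer than 200 nt was kept, 10 ng went into each library and a spike-in set was added. The protocol documents named in the labels include the manual of a SMARTer Ultra Low RNA kit. The labels do not say whether forelimbs, hindlimbs or both were taken, or at which level the limbs were parted from the trunk.

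For each library the authors deposited a table per gene and a table per transcript. Per the labels the assembly was mm10, and per the deposited sample records the annotation was GENCODE M4. The aligner and the counting program, with their versions, are not given in the sources used here, and the column layout is the layout that RSEM writes. Per the file headers the tables hold expected counts, which are estimated counts of reads that need not be whole numbers because reads matching several genes were shared among them. The deposited TPM values (transcript abundance scaled by length and library size) and posterior mean TPM values are scaled to the same total in each library, spike-ins included. The deposited FPKM values (fragments per kilobase, scaled to library size) were used only as an alternative. The deposited percent column of the transcript tables gives each transcript's share of its gene. The effective lengths in the tables were mostly 99 nt shorter than the listed lengths. The deposited interval of each TPM value covers the uncertainty of counting and of assigning reads, not the difference between pools of embryos.

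Each table had 43346 rows for mouse genes, 97 rows for spike-ins and 26248 rows with numeric identifiers. Expected counts summed to 35104685 in replicate 1 and 41757268 in replicate 2. A gene with 0 counts could still have had up to 3 counts, which is 0.0855 CPM (counts scaled to library size) in replicate 1 and 0.0718 in replicate 2. These limits cover counting error only, since amplified reads are not independent molecules. The 10 ng of starting RNA means that amplification adds noise that depth does not remove. Gene symbols and coordinates came from GENCODE M21 on GRCm38, the same build as mm10, matched on the gene identifier without its version. A symbol was found for 42462 rows, 884 rows had none, and 1 listed gene, Ahsp, had no row.

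With 1 group there was no comparison between conditions, and no p-value is given anywhere. Levels are means of the TPM of the 2 libraries with their SD (n = 2). Agreement of the replicates was described by Pearson's r and Spearman's rho across genes on log2(TPM + 1), by the number of genes over 2-fold apart, and by the biological coefficient of variation from edgeR 4.0.16 in R 4.3.3. For edgeR the expected counts were rounded to whole numbers, genes with 10 or more counts in each library were kept, TMM scaling was used and the design held an intercept only. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

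Before the data were examined, 34 gene lists, 21 pairs of genes and the rule for naming genes were fixed. Of the lists, 31 were given by member and 3 by a pattern of symbols. Ratios within a library were log2 of TPM with 0.1 added to numerator and denominator, and each was set beside a yardstick, the 95th percentile of the absolute log2 difference between the libraries over genes in the same of 20 bins of mean TPM. For the lists, log2 of replicate 2 over replicate 1 (TPM + 0.1, centred on the median gene) was taken for genes with a mean TPM of at least 1, and the median of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is called outside the random range where its percentile was under 2.5 or over 97.5. This describes 2 libraries and not a condition, and because genes of 1 tissue vary together, random lists of unrelated genes vary less than the lists would between further pools. For transcripts, the share of the most abundant transcript was computed from TPM for listed genes with a mean TPM of at least 10 and at least 2 annotated transcripts. These shares lay within 0.053 percentage points of the deposited percent column.

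Genes are named from the pairs, from the 4 highest and 2 lowest members of each list by mean TPM (the 2 highest of a pattern list), from the 20 genes of highest mean TPM outside the mitochondrial genome, from the 10 genes of highest mean TPM in no list, from the 10 genes most in favour of each library (mean TPM of at least 10 and at least 100 counts in the higher library), and from the transcript comparison. Any other gene is said to have been chosen after its values were seen.

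The programs were tested on simulated data. With counts drawn at a coefficient of variation of 0.2 and 200 genes changed 4-fold, edgeR returned 0.223 over 17251 genes, the changed genes adding to the spread. With permuted differences of 15571 genes and 50 simulated lists of 12 genes for each size, 2.0% of lists without a shift lay outside the random range, 78.0% of those shifted by 0.2 on the log2 scale and 100% of those shifted by 0.5. Permuted genes vary independently, so the simulation does not cover lists whose genes vary together. The alternatives tried were other pseudocounts and filters, size factors from DESeq2 1.42.0 and TMM-scaled counts, list means, FPKM, posterior mean TPM, TPM rescaled without mitochondrially encoded genes and spike-ins, counts not divided by length, each library alone, and, chosen after the data were seen, scaling to the spike-ins, removal of the length and GC trend, other filters for the liver-secreted list, and the dispersion of spike-ins and of genes without the muscle lists.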

Results

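Total RNA of limbs from mouse embryos at 15.5 days was sequenced from 2 separate pools, replicate 1 with 78 embryos and replicate 2 with 62 embryos. At this stage the limb has cartilage templates with the first bone, muscle with contractile fibres, stratifying skin and separated digits. The series holds this tissue alone, so the data give the composition of the limb transcriptome and the difference between the pools. Expected counts summed to 35104685 in replicate 1 and 41757268 in replicate 2, and spike-ins took 2.27% ± 0.0148 of them (SD, n = 2). A TPM of at least 1 in both libraries was found for 15007 of 43346 genes, and of at least 10 for 9222 genes.

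The most abundant transcripts came from blood, from the signal recognition particle, from mitochondria and from connective tissue. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, had 16128 ± 4459 and 16127 ± 4461 TPM (SD, n = 2), and their deposited intervals were wide (4382 to 21874 TPM for Rn7s1 in replicate 1) because reads cannot be assigned to either copy with certainty. Hba-a2, an adult alpha globin gene (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298, GRCm38), had 13937 ± 52.4 TPM. The nuclear RNA Malat1 had 5460 ± 342 TPM, Actb 4943 ± 331 TPM, the translation factor Eef1a1 4057 ± 340 TPM, the ferritin gene Ftl1 3908 ± 118 TPM and Ppia 3605 ± 69.0 TPM. Col1a1, the main collagen chain of bone and dermis (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042), had 4474 ± 647 TPM. The pseudogene Gm28437, which shares sequence with the mitochondrial genome, had 6359 ± 1364 TPM, and Gm42418, annotated as a long noncoding RNA, had 3721 ± 1030 TPM. Gm22133, a small RNA annotated inside Ftl1, had 3619 ± 424 TPM, but on only 874 and 905 counts, against 77054 and 90213 for Ftl1. Its TPM is high because TPM divides by a very short effective length, not because it had many reads. Protein-coding genes held 83.6% ± 1.43 of TPM. The 100 genes with the most reads held 18.5% ± 0.212 of gene counts, and 26.4% ± 1.46 of gene TPM when the 100 genes of highest TPM were taken instead.

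The 2 pools had closely similar transcriptomes, with Pearson's r = 0.994 and Spearman's rho = 0.955 across 43346 genes, which are not independent replicates. The biological coefficient of variation was 0.137 over 17538 genes. Their counts differed by more than counting error alone (chi-square 31.7 per degree of freedom), which amplified reads exceed in any case and which shows only that the tables did not hold 1 library under 2 names. Of 15571 genes with a mean TPM of at least 1, 608 (3.91%) differed over 2-fold, 421 being higher in replicate 1 and 187 higher in replicate 2. Among the 9480 genes with a mean TPM of at least 10 the counts were 118 and 11, and 25 of the 118 were listed muscle genes. Spike-ins with at least 100 counts varied less than genes with at least 100 counts, with an SD of log2 differences of 0.137 over 42 spike-ins against 0.279 over 13269 genes. Of 32 gene lists with enough detected members, 23 had a median outside the range of matched random lists, where about 1.6 would fall by chance if genes varied independently, 14 toward replicate 1 and 9 toward replicate 2. With list means in place of medians 12 lists lay outside.

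**Figure D1:**
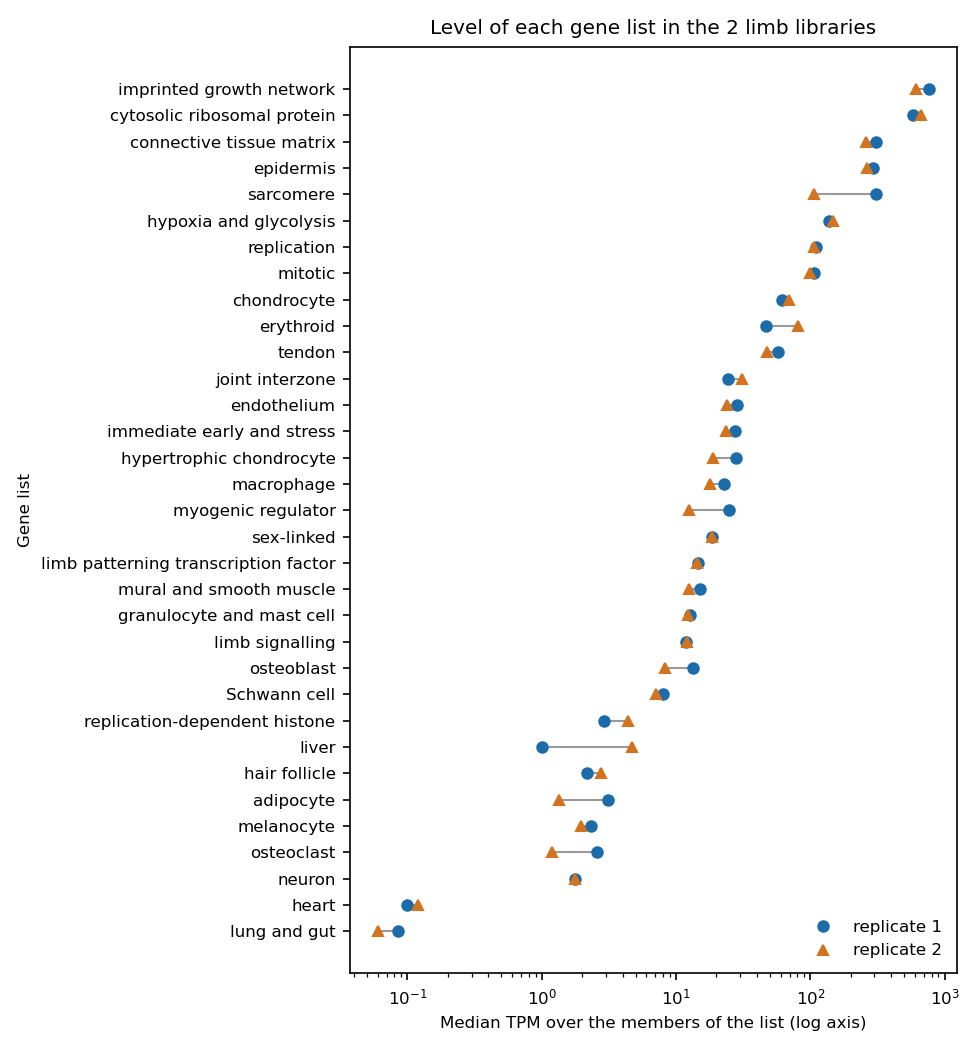
Median TPM over the members of each gene list (x axis, log scale) in replicate 1 (blue circles) and replicate 2 (orange triangles), with a grey line joining the 2 libraries; the mitochondrially encoded list, whose median is 0, is left out. The imprinted growth network has the highest median (688 TPM on average), the lung and gut list the lowest, and the widest gaps are those of the liver, sarcomere, adipocyte and osteoclast lists.

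Among the gene lists fixed beforehand, muscle genes showed the widest gap between the pools in favour of replicate 1. The sarcomere list, the contractile proteins of muscle, had a median of 309.6 TPM in replicate 1 and 106.2 TPM in replicate 2, and 27 of its 28 members were higher in replicate 1. The median difference over 25 detected members was 2.79-fold (log2 -1.48, percentile 0.0 among random lists with a central range of -0.07 to 0.07). Skeletal alpha actin, Acta1 (ENSMUSG00000031972.4, chromosome 8, 123891769 to 123894751), had 2862 TPM in replicate 1 and 779 TPM in replicate 2. The cardiac actin gene Actc1 had 1632 and 584 TPM, the myosin light chain gene Myl1 1157 and 407 TPM, and Tpm1, a tropomyosin gene also used outside muscle, 853 and 578 TPM. Among the 10 genes most in favour of replicate 1 were the light chains Myl3 (7.69-fold) and Myl2 (4.28-fold), Ckm, the muscle creatine kinase (6.0-fold), Car3, a carbonic anhydrase of slow muscle (6.13-fold), Pygm, the muscle glycogen phosphorylase (3.89-fold), the Z-disc gene Myoz1 (4.15-fold), fast troponin I Tnni2 (4.02-fold) and Arhgap36 (4.67-fold).

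The regulators of muscle formation were also higher in replicate 1, by less. The myogenic regulator list had 13 of 14 members higher there, with a median difference of 1.65-fold over 11 members (percentile 0.0). Myog, which drives differentiation of myoblasts, had 192 TPM in replicate 1 and 96.2 TPM in replicate 2. Myod1 had 48.3 and 29.5 TPM, Mymk, needed for fusion of myoblasts, 67.2 and 30.2 TPM, and Meox2, which is also active in mesenchyme, 49.4 and 42.1 TPM. Myf6, the regulator of later fibres, differed most among them (24.6 and 4.85 TPM, 4.99-fold). The progenitor genes Pax3 (0.655 ± 0.219 TPM) and Pax7 (0.540 ± 0.325 TPM) were low in both pools. Both were also higher in replicate 1, Pax3 with 0.81 and 0.5 TPM and Pax7 with 0.77 and 0.31 TPM (99 and 49 counts).

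Embryonic and neonatal isoforms predominated among the muscle myosin heavy chain genes compared. Embryonic myosin Myh3 exceeded neonatal Myh8 2.12-fold (log2 1.09 ± 0.15, SD, n = 2, yardstick 0.36) and slow Myh7 6.17-fold (log2 2.63 ± 0.23), and Myh8 exceeded the sum of the adult fast genes Myh1, Myh2 and Myh4 54.9-fold (log2 5.78 ± 0.81, yardstick 1.90). Myog exceeded Myod1 3.59-fold (log2 1.84 ± 0.20). Balances within the thin filament were closer to even and not beyond the yardstick in both libraries: Actc1 over Acta1 was -0.81 in replicate 1 and -0.41 in replicate 2 on the log2 scale, fast Tnnt3 over slow Tnnt1 was -0.07 and -0.58, and slow Tnni1 over fast Tnni2 was 0.13 and 0.77. Pax7 over Pax3 was -0.31 ± 0.34, under the yardstick of 1.90, and 0.25 with counts not divided by length.

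**Figure D2:**
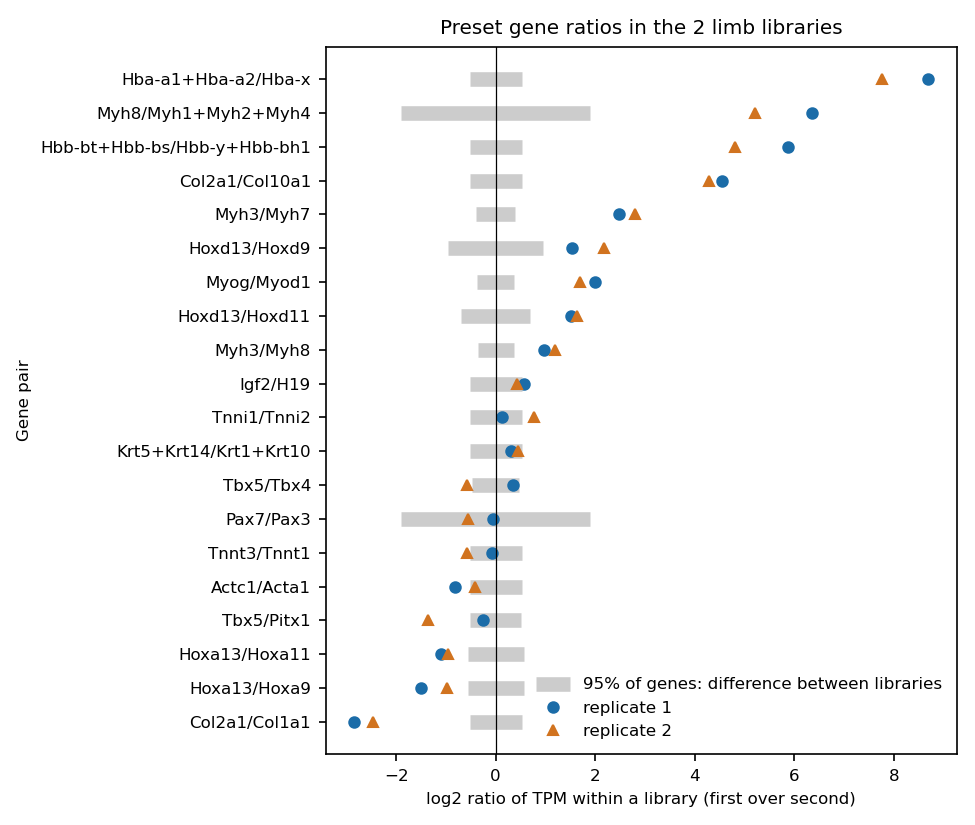
Log2 ratio of TPM (x axis) for the 21 preset pairs except Xist over Ddx3y, which is left out (y axis, first gene or sum over second). Values are shown within replicate 1 (blue circles) and replicate 2 (orange triangles). The grey bar spans plus and minus the yardstick, the log2 difference between libraries that 95% of genes of similar level stay within. In 12 pairs both libraries lie beyond the bar on the same side.

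Cartilage was prominent and alike in the pools. The chondrocyte list had a median of 65.7 ± 5.52 TPM, 20 of 21 members reached 10 TPM in both libraries, and the median difference was 1.04-fold toward replicate 2, inside the random range (percentile 97.0). Col2a1, the main cartilage collagen, had 710 ± 30.2 TPM, Col9a3 350 ± 3.65 TPM and Cnmd 197 ± 1.25 TPM, while Ucma, another gene of the list, had 12.2 TPM in replicate 1 and 4.56 TPM in replicate 2. Col2a1 exceeded Col10a1, the collagen of hypertrophic chondrocytes, 21.4-fold (log2 4.42 ± 0.18). In the hypertrophic chondrocyte list Pth1r (67.2 and 88.7 TPM), Col10a1 (29.4 and 37.2 TPM) and Ihh (4.04 and 6.76 TPM) were higher in replicate 2, Panx3 was alike (18.9 ± 0.092 TPM), and the matrix protease gene Mmp13 was higher in replicate 1 (28.1 and 11.8 TPM). The median of the differences in that list lay toward replicate 2 (log2 0.36, percentile 99.9), but their mean of 0.07 was inside the random range and the median TPM was higher in replicate 1 (28.1 and 18.9 TPM). The joint interzone list had a median of 27.6 ± 4.43 TPM and no difference outside the random range (percentile 32.5), with Sfrp2 at 250 ± 58.2 TPM and Gdf5, a marker of forming joints, at 43.9 ± 8.63 TPM.

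Bone genes were higher in replicate 1. In the osteoblast list 12 of 14 members were higher there, by a median of 1.48-fold over 12 detected members (percentile 0.0). Ibsp (388 and 226 TPM) and Spp1 (286 and 118 TPM), which encode proteins of mineralizing matrix, and Alpl (58.0 and 35.8 TPM), the alkaline phosphatase of bone, followed this order. Mepe and Sost, genes of osteocytes, stayed under 1 TPM in both libraries. In the osteoclast list 9 of 11 members were higher in replicate 1, by a median of 1.52-fold over 6 detected members (percentile 0.01), with the collagen-degrading protease genes Ctsk (127 and 81.2 TPM) and Mmp9 (44.5 and 18.4 TPM), and Acp5 (38.8 and 25.4 TPM). Nfatc1, which is active in other cells too, had 28.3 and 33.8 TPM.

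Connective tissue genes were among the most abundant of the limb. The connective tissue matrix list had a median of 282 ± 33.5 TPM and held 1.70% ± 0.211 of TPM, with Sparc at 3345 ± 648 TPM, Col3a1 at 3010 ± 307 TPM and Col1a2 at 2374 ± 245 TPM. Its median was 1.10-fold higher in replicate 1 (percentile 0.02; inside the random range for the mean). Col1a1 exceeded Col2a1 6.27-fold (log2 of Col2a1 over Col1a1 -2.65 ± 0.27). The tendon list had a median of 52.6 ± 6.48 TPM and included Tnmd at 276 ± 22.9 TPM and Kera at 190 ± 0.276 TPM, and its median difference of 1.11-fold toward replicate 1 (percentile 2.13) was inside the random range for the mean and without the filter on TPM. The adipocyte list was low and had 9 of 10 members higher in replicate 1, by a median of 1.5-fold over 6 detected members (percentile 0.03). Fabp4, a fatty acid binding protein, had 55.4 TPM in replicate 1 and 22.8 TPM in replicate 2, while Ebf2 had 17.3 ± 1.17 TPM and Ucp1, the uncoupling protein of brown fat, was near 0.

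Skin genes were abundant, and as a list they differed little between the pools. The epidermis list had a median of 277 ± 19.4 TPM and a median difference of 1.0-fold (percentile 50.2). Krtdap, a gene of differentiating keratinocytes, had 2925 ± 234 TPM, basal Krt14 1066 ± 51.5 TPM, Krt15 1030 ± 44.0 TPM and suprabasal Krt1 926 ± 87.7 TPM. Basal Krt5 and Krt14 together exceeded suprabasal Krt1 and Krt10 1.29-fold (log2 0.37 ± 0.09, under the yardstick of 0.52, and -0.04 with counts not divided by length). Ivl, a protein of the cornified envelope, had 21.9 TPM in replicate 1 and 15.8 TPM in replicate 2, Flg had under 1 TPM in both, and Lce1m, a late cornified envelope gene (ENSMUSG00000027912.8, chromosome 3, 93017810 to 93019060), differed more than any other gene that met the level and count minimum, with 20.8 and 1.89 TPM (10.5-fold). The hair follicle list was low (median 2.48 ± 0.410 TPM) apart from Krt17 (221 ± 2.39 TPM), and its difference toward replicate 2 (log2 0.35, percentile 97.7) was inside the random range under 4 of 6 alternatives. The melanocyte list (median 2.16 ± 0.269 TPM, log2 -0.49, percentile 2.23) had Pmel at 7.57 and 4.98 TPM and Dct at 6.45 and 3.65 TPM, and was inside the range for the mean.

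Blood genes made up 3.12% ± 0.0478 of TPM, nearly all of it adult globin. Adult Hbb-bs had 6896 ± 9.32 TPM, Hbb-bt 4681 ± 366 TPM and Hba-a1 5193 ± 18.0 TPM. The embryonic globin genes were higher in replicate 2, Hbb-y with 190 TPM in replicate 1 and 417 TPM in replicate 2 (2.20-fold) and Hba-x with 46.5 and 87.7 TPM (1.89-fold). Adult over embryonic beta globin was 58.8-fold in replicate 1 and 28.1-fold in replicate 2 (log2 5.34 ± 0.75), and adult over embryonic alpha globin was 412-fold and 217-fold (log2 8.22 ± 0.65). The erythroid list had 9 of 13 members higher in replicate 2, by a median of 1.43-fold over 12 members (percentile 100), with the erythroid regulator Klf1 at 1.19 and 2.07 TPM and the membrane protein gene Epb42 at 0.400 and 0.850 TPM.

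Other cells of the limb were detected at moderate levels. The endothelium list had a median of 26.3 ± 3.09 TPM and was 1.16-fold higher in replicate 1 (percentile 0.01), with Egfl7 at 96.0 ± 10.3 TPM. The macrophage list had a median of 20.2 ± 3.33 TPM and was 1.18-fold higher in replicate 1 (percentile 0.0), with Lyz2 at 114 ± 17.3 TPM and C1qb at 66.3 ± 5.82 TPM. The mural and smooth muscle list was 1.33-fold higher in replicate 1 (median 13.8 ± 1.95 TPM, percentile 0.01), with Acta2, which developing skeletal muscle also expresses, at 301 and 199 TPM. Each of these differences was inside the random range when list means were used. The granulocyte and mast cell list (median 12.4 ± 0.255 TPM, percentile 5.36, outside the range with the length and GC trend removed) contained the mast cell protease gene Cpa3 at 265 ± 11.7 TPM. The Schwann cell list had a median of 7.58 ± 0.608 TPM (log2 -0.23, percentile 0.65; inside the range in 3 of 6 alternatives) and the neuron list 1.77 ± 0.0106 TPM (percentile 75.8), with Map2 at 18.5 ± 0.658 TPM and Stmn2 at 9.84 ± 0.035 TPM.

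Genes of limb position were shifted toward replicate 2 as a list. The limb patterning transcription factor list had a median of 14.4 ± 0.191 TPM, 21 of 29 members were higher in replicate 2, and the median difference was 1.16-fold (percentile 100), although the median TPM was nearly equal (14.5 and 14.3 TPM). Msx1 had 122 ± 12.8 TPM, Prrx1 90.3 ± 5.59 TPM and Hoxa10 81.0 ± 10.7 TPM. The digit genes Hoxa13 (9.27 and 14.3 TPM) and Hoxd13 (17.6 and 26.6 TPM) were higher in replicate 2, as were the hindlimb genes Pitx1 (19.1 and 30.8 TPM) and Tbx4 (12.6 and 18.0 TPM), whereas the forelimb gene Tbx5 had 16.0 and 12.02 TPM. Tbx5 over Tbx4 was accordingly 1.27-fold in replicate 1 and 0.669-fold in replicate 2, and Tbx5 over Pitx1 was 0.840-fold and 0.392-fold. Neither was beyond the yardstick in both libraries, and with counts not divided by length their mean log2 ratios were 0.23 and 0.00. From replicate 1 to replicate 2, however, the log2 ratios shifted by -0.93 and -1.1. Their yardsticks were 0.47 and 0.51, which describe differences of single genes and not of ratios. Hoxd13 exceeded Hoxd11 2.99-fold (log2 1.58 ± 0.08) and Hoxd9 3.61-fold (log2 1.85 ± 0.46), while Hoxa11 exceeded Hoxa13 2.03-fold (log2 of Hoxa13 over Hoxa11 -1.02 ± 0.10) and Hoxa9 exceeded it 2.35-fold (log2 -1.24 ± 0.36). The limb signalling list had a median of 12 ± 0.209 TPM and a difference inside the random range (percentile 79.1), with Wnt5a at 84.5 ± 0.297 TPM and Dusp6 at 56.6 ± 4.19 TPM, and Fgf8, the signal of the early apical ridge, had 0.340 ± 0.113 TPM on 6.0 and 7.0 counts.

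Growth and proliferation genes were expressed strongly. The mitotic list had a median of 103 ± 5.73 TPM and the replication list 108 ± 2.13 TPM, both with differences inside the random range (percentiles 41.8 and 89.7), with Cdk1 at 292 ± 12.4 TPM and Pcna at 173 ± 0.113 TPM. The imprinted growth network had a median of 688 ± 114 TPM, and 10 of 10 members were higher in replicate 1, by a median of 1.16-fold (percentile 0.01), among them Mest at 1570 ± 178 TPM, Meg3 at 1455 and 974 TPM and Igf2 at 1123 ± 112 TPM. Igf2 exceeded H19 1.41-fold (log2 0.50 ± 0.11, under the yardstick of 0.52). The hypoxia and glycolysis list had a median of 142 ± 7.80 TPM and a difference inside the random range (percentile 38.7), although Aldoa, which muscle uses heavily, had 1018 and 696 TPM. The immediate early and stress list had a median of 25.4 ± 2.66 TPM, with Jun at 92.2 ± 3.92 TPM and Fos at 36.3 ± 6.23 TPM, and its median was 1.21-fold higher in replicate 1 (percentile 0.02; inside the range for the mean). Female and male transcripts were both present, with Xist at 29.6 ± 5.27 TPM and the Y-linked Ddx3y at 18.8 ± 0.502 TPM; Xist over Ddx3y was 1.56-fold (log2 0.64 ± 0.30), and the sex-linked list (log2 0.31, percentile 99.5) was inside the random range with TMM-scaled counts and for the mean.

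Ribosomal, mitochondrial and histone transcripts were higher in replicate 2. Of 89 genes with symbols of cytosolic ribosomal proteins, 5 of them annotated as pseudogenes, 81 were higher there, by a median of 1.17-fold over 87 detected genes (percentile 100), with Rpl41 at 2833 and 3485 TPM. Of the 37 mitochondrially encoded genes 15 had reads above 1 TPM, and 14 of these were higher in replicate 2, by a median of 1.20-fold (percentile 100). The gene mt-Atp6 had 5592 and 6584 TPM with overlapping deposited intervals, and mt-Atp8 had 4252 and 4882 TPM with intervals that did not overlap. The replication-dependent histone list, whose transcripts lack a poly(A) tail, was 1.31-fold higher in replicate 2 over 50 detected genes (percentile 100), with Hist1h2ap at 2201 and 2498 TPM, although copies of these genes share reads. Rn7sk, the RNA that holds back transcription elongation, was 1.89-fold higher in replicate 2 and Rn7s1 1.49-fold, the deposited intervals of Rn7s1 overlapping, as were the classes of mitochondrial rRNA (2655 and 4343 TPM) and ribozymes (69.6 and 106 TPM), while snoRNA (462 and 482 TPM), snRNA (178 and 190 TPM) and scaRNA (22.8 and 20.3 TPM) were nearly level.

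Markers of organs that a dissection could carry over were low, and those of liver differed between the pools. All 9 genes of the liver list were higher in replicate 2, by a median of 4.64-fold over 7 detected genes (log2 2.21, percentile 100 among random lists with a central range of -0.27 to 0.28). Afp, the fetal plasma protein alpha-fetoprotein (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907), had 3.41 TPM in replicate 1 and 21.5 TPM in replicate 2 on 151 and 1162 counts, Alb 2.14 and 10.3 TPM, Apoa2 3.08 and 14.4 TPM and Apoa1 3.45 and 11.6 TPM. The list as a whole held 14.6 TPM in replicate 1 and 69.0 TPM in replicate 2. The heart list had a median of 0.110 ± 0.0141 TPM, with too few detected genes to set beside random lists. The atrial light chain Myl7 (5.20 and 3.06 TPM) and Myh6 (1.31 and 0.160 TPM) were higher in replicate 1, as was the sarcomere list (2.79-fold). They rested on few counts, 57 and 41 for Myl7 and 126 and 26.4 for Myh6. The other members, Nppa, Nkx2-5, Tbx20 and Ryr2, stayed under 1 TPM in both libraries, so heart tissue in replicate 1 is not shown. The lung and gut list had a median of 0.0725 ± 0.0177 TPM, and Nkx2-1 and Cdx2 had 0 counts in both libraries. Besides Afp, Hbb-y, Hba-x and Rn7sk, the 10 genes most in favour of replicate 2 were the histone genes Hist3h2ba (2.43-fold) and Hist1h2ak (2.13-fold), Alcam (2.15-fold), Ccdc8 (2.08-fold), Crebzf (2.01-fold) and Gm12070 (1.89-fold).

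**Figure D3:**
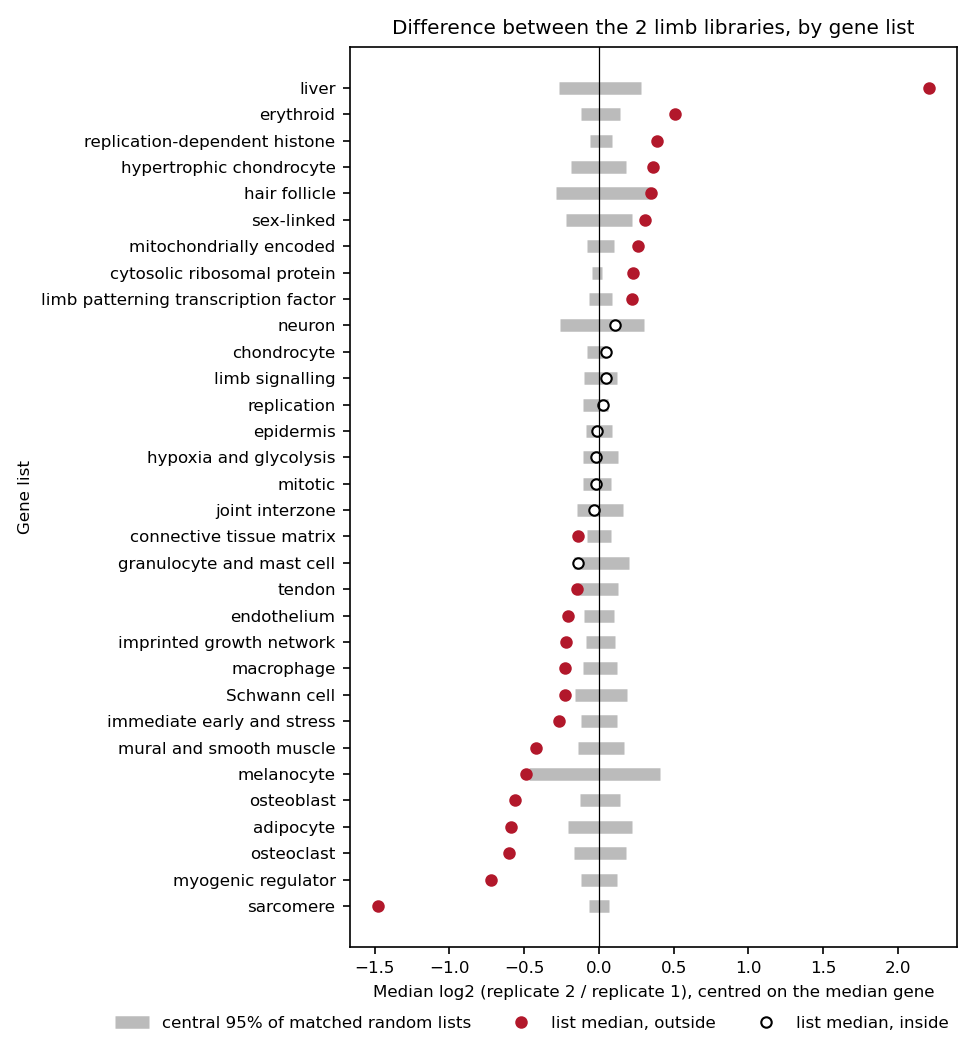
Median log2 of replicate 2 over replicate 1 (x axis, centred on the median gene) for each gene list (y axis), with filled red points outside and open points inside the central 95% of 10000 expression-matched random lists (grey bars). Liver (2.21) and sarcomere (-1.48) lie farthest out at the opposite ends, and 9 of the 32 lists lie inside their bars.

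Most listed genes used the same main transcript in both pools. Of 222 listed genes with a mean TPM of at least 10 and several annotated transcripts, 213 had the same most abundant transcript in both libraries, and the median share of that transcript was 81.5% in replicate 1 and 80.1% in replicate 2. Col1a1 came almost entirely from Col1a1-201 (99.5% ± 0.09), Hba-a2 from Hba-a2-201 (99.99% ± 0.0), while Sparc was split, with Sparc-205 at 46.5% ± 2.17, and so were Hbb-bs, with Hbb-bs-202 at 54.4% ± 2.67, and Hba-a1, with Hba-a1-202 at 76.7% ± 0.32. The most abundant transcript differed in 9 genes. For Tpm1, tropomyosin transcript Tpm1-205 held 53.4% in replicate 1 and 27.1% in replicate 2, where Tpm1-213 led with 34.9%. For Igf2, Igf2-203 led in replicate 1 with 37.5% and Igf2-208 in replicate 2 with 42.4%, and for Tpm2, Tpm2-202 led in replicate 1 with 49.0% and Tpm2-203 in replicate 2 with 48.8%. H19 and Rpl11 also differed. Shares of transcripts that overlap along most of their length are estimates with wide uncertainty.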

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

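Reads were present in a part of the tables that no comparison used. The 26248 rows with numeric identifiers, of median length 73.0 nt, had 41.0 counts in replicate 1 and 75.6 counts in replicate 2, which is more than the 3 counts that an observed 0 would still allow. The reads fell in 11 rows, the shortest of 114 nt, and a single row of 255 nt held 30.0 and 58.0 of them, itself more than 3. Of all 26248 rows, 26185 had an effective length of 0 and could receive no reads, so the counts say nothing on the RNAs they stand for. With 2 libraries in 1 group, neither a search for outlying samples nor a comparison of effects between groups could be made.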

How the results depend on the processing

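Of the alternative values for single genes, lists and ratios, 529 stayed within the spread set for their kind, 74 moved beyond it and 4 changed sign. Another 642 stayed within it by construction, since a library alone lies within the SD of 2 and scaling to the spike-ins moves all genes alike, and they test nothing. The correlation of the replicates was 0.994 and stayed within 0.01 of that with a pseudocount of 0.1, FPKM, posterior mean TPM or genes of mean TPM at least 1, but was 0.973 with a pseudocount of 0.01. The share of genes over 2-fold apart was 3.91% (608 genes) and 1.36% (129 genes) with a mean TPM of at least 10. The 100 highest genes held 18.5% of counts and 26.4% of TPM. The biological coefficient of variation of 0.137 was alike with DESeq2 size factors, without a count filter and without muscle genes, and 0.0513 for spike-ins (the last 2 settings chosen after seeing the data). Lists outside the random range numbered 23, and 12 with list means; 12 lists were outside under all 6 alternatives, of which scaling to the spike-ins changed 0 calls: sarcomere, myogenic regulator, osteoblast, osteoclast, adipocyte, imprinted growth network, liver, erythroid, limb patterning, ribosomal, mitochondrial and histone. The cause of these changes between settings was not tested. With counts not divided by length, the means of 4 ratios not beyond the yardstick in both libraries moved to or across 0: Pax7 over Pax3 from -0.31 to 0.25, Tbx5 over Tbx4 from -0.12 to 0.23, Tbx5 over Pitx1 from -0.80 to 0.00, and basal over suprabasal keratins from 0.37 to -0.04, a change that the gene lengths set. Of the other ratios 7 moved beyond their SD, most of all Xist over Ddx3y from 0.64 to 2.77 and Col2a1 over Col10a1 from 4.42 to 5.07, and 10 stayed. TPM rescaled without mitochondrially encoded genes and spike-ins raised 11 list levels beyond their SD and left 22 within it. Tbx5 over Tbx4 ranged from -0.58 to 0.35 with either library alone. Differences between the libraries cannot be given with a library left out, and the posterior mean moved 40 of 241 named gene levels by more than their SD, Mitf from 2.5 to 22.5 TPM. No paired analysis was possible because there is 1 group. Depth limits statements on genes with few counts.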

Other observations

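All tests in this part were chosen after the differences between the pools had been seen, and the families and genes named here were chosen after their values were seen. The outcome to be expected from the barrier, oncofetal, trunk and liver-secreted lists was written down before the members of those lists had been looked at, but after related genes had been seen, among them Lce genes, liver genes and the distal Hox genes, so it was not a blind guess. The 2 groups of Hox genes were formed after the trunk list.

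The late cornified envelope genes, a cluster on chromosome 3 that is switched on in the outermost keratinocytes, were higher in replicate 1 in 14 of 15 detected members, by a median of 2.90-fold (percentile 0.0), and 11 of them by over 2-fold. Lce1c had 13.0 TPM in replicate 1 and 2.40 TPM in replicate 2, Lce1a2 12.6 and 2.62 TPM, and the most abundant member, Lce3f, 65.7 and 48.0 TPM. Lce3c went the other way, with 3.97 and 9.26 TPM. The epidermis list as a whole lay at percentile 50.2. Of 13 genes of muscle energy metabolism, 12 were higher in replicate 1, by a median of 3.39-fold, but Ckm, Car3 and Pygm entered this group because their difference had been seen. Among the others, Eno3, the muscle enolase, had 213 and 58.7 TPM, Cox6a2 116 and 33.3 TPM, and Ckmt2 12.7 and 2.04 TPM. Adipoq, a hormone of fat cells, had 2.10 and 0.0800 TPM.

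The Hox genes divided by position in their clusters. Of the genes of paralogue groups 1 to 8, which are expressed in the trunk and the proximal limb, 9 of 10 detected members were higher in replicate 1 (median 1.26-fold, percentile 0.78). Among these 9 was Hoxc5, which was nearly level at 1.89 TPM in replicate 1 and 1.85 TPM in replicate 2. Of groups 9 to 13, 10 of 13 were higher in replicate 2 after centring on the median gene (median 1.13-fold, percentile 98.9). That count includes Hoxc12, which was nearly level at 3.27 TPM in replicate 1 and 3.23 TPM in replicate 2. No detected gene of either set was over 2-fold higher in replicate 1. Groups 9 and 10 were mixed. Hoxa9 (26.2 and 28.2 TPM), Hoxa10 (73.4 and 88.5 TPM) and Hoxd10 (10.5 and 11.9 TPM) were higher in replicate 2. Hoxd9 (6.03 and 5.82 TPM) and Hoxc10 (5.08 and 4.58 TPM) were higher in replicate 1. Many of the second set also belong to the limb patterning list, and the first set makes up most of the trunk and proximal list below, so these are not separate evidence.

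Muscle genes were higher in replicate 1, by a median of 2.79-fold in the sarcomere list. A bias of transcript length and GC content is argued against as the whole cause, since the median log2 difference was -1.47 with that trend removed (25 of 25 detected members had a GC content). A larger share of muscle of the same make-up would leave the ratios between contractile isoforms alone, early to late or slow to fast. The median shift was 0.46 in 4 chosen pairs (central range of random pairs -0.24 to 0.27). It was 0.36 in all 6 preset pairs of contractile isoforms (-0.24 to 0.22), which argues against an unchanged make-up as the whole cause. The largest of the 4 shifts were those of slow over fast troponins, Tnnt1 over Tnnt3 (0.51) and Tnni1 over Tnni2 (0.64). A change from early to late isoforms is therefore not shown apart from one between slow and fast. Some of the 6 pairs share Myh3 or Myh8, whereas the random pairs were of unrelated genes. Of the 6 pairs 5 shifted up in replicate 2, Myh3 over Myh8 by only 0.21 and Myh3 over Myh7 by 0.32, whereas Myh8 over the adult fast myosins, which were near 1 TPM, shifted by -1.15, under its yardstick of 1.90. A larger share combined with a changed state of the fibres stays open, and the design names no group by which the pools differ, so no explanation from the design could be tested.

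Some late genes, picked after their values were seen and not from a fixed list, were higher in replicate 1 (Myf6, Ckm, Spp1, most Lce genes, and adult relative to embryonic globin), while the hypertrophic chondrocyte list lay toward replicate 2 by its median (log2 0.36, percentile 99.9) but not by its mean (0.07), with Mmp13 higher in replicate 1. A hypothesis is that the pool of replicate 1 was further advanced in development although both are labelled 15.5 days. A list of 23 other barrier genes of the skin lay on the side that this hypothesis predicts, at percentile 0.81 over 21 detected members. Its median difference was small (log2 -0.11), and the median TPM of 24.3 and 27.0 lay the other way. After centring on the median gene, 14 of 21 were higher in replicate 1, a count that leaves out Tgm3 (2.75 and 2.71 TPM). The hypothesis also predicts that genes that decline in late gestation, such as Igf2bp1, are lower in replicate 1. That shift was not seen. The list lay inside the random range, at percentile 82.75 over 6 detected members (log2 0.07, central range -0.17 to 0.15). Its median TPM was nearly level, at 32.9 in replicate 1 and 33.2 in replicate 2. After centring, 4 of the 6 were higher in replicate 2. A true shift smaller than that range could not have been told from none. More proximal tissue in replicate 1 may also contribute, since a list of trunk and proximal genes lay at percentile 0.64. Of its 12 detected members 10 were higher there, 9 of 9 Hox genes (Hoxc5 nearly level) but 1 of 3 others. Hoxc8, left to the limb patterning list, was higher in replicate 2. If blood is alike along the limb, such tissue would not alter the adult-to-embryonic globin ratios. Their median shift was -1.0 against a central range of -0.66 to 0.68. That shift, in 2 pairs, was already known and is part of the pattern to be explained, so it is no independent test against proximal tissue. Stage and dissection therefore stay open side by side, as does the mix of forelimbs and hindlimbs, which was not tested apart from the ratios of Tbx5, Tbx4 and Pitx1.

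Liver genes were higher in replicate 2, by a median of 4.64-fold. A candidate explanation is a trace of liver tissue in the pool of replicate 2: a second list of 20 liver-secreted proteins lay at percentile 99.44, with 7 of 11 detected members higher in replicate 2, among them Ambp (0.420 and 2.26 TPM), Kng1 (0.370 and 1.64 TPM) and Apoh (0.330 and 1.68 TPM), while the 3 members of at least 10 TPM in both libraries had 36.6 and 45.6 TPM (Apoc1), 28.1 and 35.8 TPM (Trf) and 20.4 and 17.6 TPM (Rbp4). Without the filter on TPM 15 of 20 members were higher in replicate 2 (percentile 100), but the 8 members of at least 1 TPM in both libraries split 4 to 4 (log2 0.02, percentile 53.1), so the list rests on genes near the floor in replicate 1. The most abundant liver transcripts stayed low in replicate 2 as well (Afp 21.5 TPM, Alb 10.3 TPM), and yolk sac, which makes several of the same proteins, and a difference in the limb itself were not tested.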
